A study of Mus musculus with 36 samples.

How the data were processed

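RNA was sequenced from 2 mouse breast cancer cell lines, AT-3 (from an MMTV-PyMT mammary tumour) and E0771 (from a mammary adenocarcinoma). Per the labels' protocols, cells were seeded for 24 h in 6-well dishes and then treated for 24 h with DMSO, 10 µM NS11021, 10 µM BMS204352, 40 mM KCl, or KCl with either compound. NS11021 is an opener of the BK potassium channel, which Kcnma1 encodes, and BMS204352 opens BK and KCNQ potassium channels. Each of the 12 groups held 3 libraries, 36 in all. Per the labels' protocols, RNA was taken with Qiagen RNeasy and libraries were made with the NuGen Universal Plus mRNA kit.

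The deposited table holds whole-number read counts per gene. Per the submitters' processing notes, the authors aligned reads to GRCm38 with STAR and made the counts with featureCounts; versions and the counting strand are not given in the sources used here. All 36 columns were matched to their samples by title and 0 columns were left over. The table held 32287 gene IDs. The 2 IDs of human form, with 6 counts in all, were left out, which left 32285 mouse IDs. Symbols were matched to the table through gene IDs in the GENCODE vM21 annotation of GRCm38; 127 IDs had no symbol and held 0.0415% of counts. For 26 IDs the symbol is also held by an ID with more counts, and the ID with more counts was used under that symbol. Among counts from 1 to 10, 84.5% were even, a pattern left when the mates of a read pair are counted apart, so the tests of genes, though not those of lists, were also run on halved counts.

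Counts per library summed to between 31.2 and 52.6 M. All sums, CPM (counts per M of library total), fold changes and tests were computed here from the deposited counts. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), counts were normalized by the trimmed mean of M-values (factors 0.984 to 1.02), and edgeR's quasi-likelihood test with robust dispersions was fitted to the 18 libraries of each line. The common dispersion was 0.0136 in AT-3 and 0.005 in E0771, a coefficient of variation between replicates of 0.116 and 0.0707. The fit to all 36 libraries served only for differences between the lines. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene or list passed at an adjusted p below 0.05. Values after ± are standard errors (SE) of log2 fold changes from the fit, or standard deviations (SD) of 3 libraries beside CPM. Floors and 95% intervals cover counting error and the fitted spread between libraries only; a floor is given as 3 counts over the summed library totals.

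The 21 comparisons were KCl and each compound against DMSO, each compound with KCl against KCl, the compounds against each other with and without KCl, the interaction of KCl with each compound, all per line, and the difference between lines in the effects of KCl, NS11021 and BMS204352. These comparisons, the tests, the filters, the gene lists with their members and the alternatives were chosen before the data were examined, save those named as added.

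The 29 lists were MRTF-SRF targets, immediate early genes, YAP-TEAD targets, calcium-NFAT and CREB targets, potassium channels and pumps, calcium entry and handling, the hypertonic (NFAT5) response, the integrated stress response (ATF4), ER chaperones, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia (HIF1), nuclear genes of oxidative phosphorylation, oxidative stress (NRF2), aryl hydrocarbon receptor targets, heat shock, the metal response, p53 targets, G1/S and DNA replication, G2/M and mitosis, NF-kB and chemokines, interferon response and antigen presentation, collagens and matrix, adhesion and cortical cytoskeleton, epithelial markers, mesenchymal transition markers, and markers of fibroblasts, leukocytes and endothelium as other cell types. Lists with at least 5 tested members were tested with camera (limma, through edgeR) at a preset correlation of 0.01, and again with the correlation estimated from the data. Members were counted as past the threshold over all tested genes, and also with p-values adjusted over the list alone.

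Named genes followed a rule: the index genes Kcnma1, Srf, Mrtfa, Mrtfb, Acta2, Actb, Vcl, Myl9, Tagln, Cnn1, Ccn1 and Ccn2; the 6 largest rises and falls for KCl and each compound against DMSO, and the 3 largest for other comparisons, among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the libraries compared; and up to 4 members with the smallest adjusted p of each list that passed or held at least 4 members past the threshold. Fewer are named where space is short, in that order. Gene models without a name were passed over. Some genes that this rule would name are not reported here.

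The alternatives were DESeq2's Wald test, DESeq2 size factors, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, only the libraries of the groups compared, and leaving out each library in turn. Halved counts, leaving out the replicate 3 libraries of BMS204352 and KCl+BMS204352, and leaving out single libraries in tests of the HIF1 and ER chaperone lists were added after seeing the data. To set the agreement of 2 compounds that share DMSO or KCl libraries against what the sharing alone gives, 20 simulated data sets without a compound effect were analysed. The scripts were tested on simulated data with 200 seeded genes. At log2 changes of 0.30, 0.58, 1.00 and 2.00 the test of NS11021 against DMSO recovered 14, 76, 84 and 96% of them in AT-3 and 54, 88, 90 and 100% in E0771, with 9 and 10 false calls. For the interaction of KCl and NS11021 the shares were 8, 42, 84 and 92% in AT-3 and 28, 66, 82 and 94% in E0771. A planted list was recovered in both lines and 0 other lists were called. The simulated genes were drawn independently, so this cannot show how often lists of correlated genes are called falsely. Samples were also regrouped in every other split of 3 against 3, or in 100 drawn splits for comparisons of 4 groups.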

Results

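Gene expression was measured by RNA sequencing in 36 libraries of AT-3 and E0771 mouse breast cancer cells, 3 for each of 6 treatments per line. Library totals were 38.5 to 52.6 M counts in AT-3 and 31.2 to 47.9 M in E0771, and 14772 and 13357 genes were tested. The series concerns expression driven by the actin-regulated coactivator MRTFA (Mrtfa) and its partner SRF (Srf), so their genes and classic targets were followed throughout.

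The replicate 3 libraries of BMS204352 stood apart in both lines, and that of KCl+BMS204352 did in AT-3. In AT-3 the 3 BMS204352 libraries lay at 17.2, 22.1 and 65.9 on the first principal component (16.2% of variance) and KCl+BMS204352 at −3.16, 1.31 and 30.1. In E0771 the BMS204352 libraries lay at 3.37, −1.07 and 30.2 on PC3 (5.43%), and KCl+BMS204352 at 6.35, 11.3 and 15.9. Each main count for BMS204352 is therefore also given without these 4 libraries. They also enter the dispersions shared by the 18 libraries of each line, so they can bear on the KCl and NS11021 counts. Those counts were not run without them. With only the libraries of the groups compared, AT-3 gave 952 genes for KCl, 83 for NS11021 and 23 for KCl+NS11021 against KCl. With all 18 libraries it gave 714, 11 and 3. Mitochondrial transcripts made up 0.687 to 0.792% of counts in AT-3 KCl+BMS204352 against 0.490 to 0.608% in the other AT-3 libraries. The share was 0.789 to 1.03% in E0771 KCl+BMS204352 against 0.522 to 0.887% in the other E0771 libraries, so the ranges overlapped, though not with KCl+NS11021 (0.725 to 0.750%) or KCl alone (0.678 to 0.739%). It moved with that treatment, so RNA quality and treatment cannot be told apart in AT-3, nor among the KCl libraries of E0771.

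The mRNA of the BK channel, the stated target of NS11021, was scarce. Kcnma1 had 2 to 16 counts per library in AT-3 (0.152 ± 0.0836 CPM in DMSO) and 0 to 26 in E0771 (0.0325 ± 0.0563 CPM in DMSO, n = 3), and did not reach the filter in the E0771 fit. Other potassium channels were higher: Kcnn4, an intermediate-conductance calcium-activated channel, had 92.7 CPM in AT-3 and 124 in E0771 DMSO libraries, and the KCNQ channel gene Kcnq5 had 4.52 and 19.8 CPM. Kcnk1, a leak channel, had 112 CPM in AT-3 DMSO libraries and 0 counts in all 18 E0771 libraries (floor 0.00434 CPM). On GRCm38 (GENCODE vM21) the index genes lie at chr14:23289431-24014491 (Kcnma1), chr17:46548329-46556175 (Srf), chr15:81012281-81190757 (Mrtfa), chr16:13256481-13417529 (Mrtfb), chr19:34241090-34255590 (Acta2), chr5:142903115-142906754 (Actb), chr14:20929398-21033676 (Vcl), chr2:156775420-156781658 (Myl9), chr9:45929619-45936058 (Tagln), chr9:22099216-22109630 (Cnn1), chr3:145646976-145649981 (Ccn1) and chr10:24595442-24598683 (Ccn2). Tagln shares 67.9% of its exon bases with another gene, so its counts depend on the strand used, which is not stated. Tagln passed the threshold in 0 of the 21 comparisons.

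**Figure D1:**
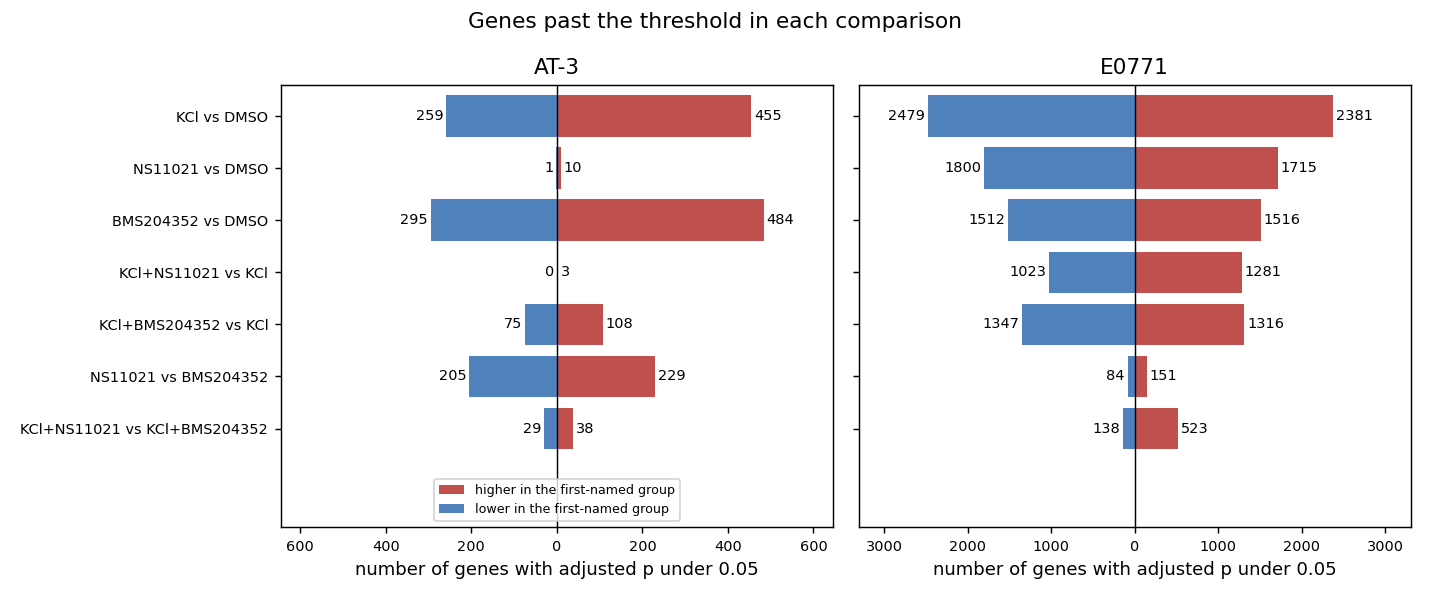
Number of genes higher (right) and lower (left) at adjusted p below 0.05 in 7 comparisons, AT-3 and E0771 in separate panels, 3 libraries per group. KCl against DMSO gave 714 genes in AT-3 and 4860 in E0771.

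The treatments held no control matched to KCl for osmolarity or chloride. Effects of potassium, chloride and osmolarity therefore cannot be told apart in any KCl comparison. With 40 mM KCl in AT-3, Aqp1, a water channel, had the largest rise, 18.2-fold (log2 4.19 ± 0.60, adjusted p = 0.00172, n = 3 against 3), from 4.63 ± 1.31 to 84.4 ± 24 CPM. Next came Gal3st1, which makes sulfated glycolipids (2.82 ± 0.24), the organic anion transporter Slco4a1 (2.11 ± 0.22), the glycosyltransferase Galnt18 (1.88 ± 0.24), the calcium channel subunit Cacng4 (1.79 ± 0.25) and the protease inhibitor Serpinb9 (1.66 ± 0.17). The largest falls were in the neurotrophic receptor subunit Gfra2 (−1.18 ± 0.24), the metabolic coactivator Ppargc1b (−0.94 ± 0.19), the glutamate transporter Slc1a1 (−0.92 ± 0.23), the protease inhibitor Slpi (−0.92 ± 0.12), Sned1 (−0.90 ± 0.18) and the collagen Col16a1 (−0.89 ± 0.06). In the hypertonic (NFAT5) list 7 of 16 members were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 3.12e-18, and adjusted p = 0.00189 with an estimated correlation), with Sgk1 (1.35 ± 0.11), the sorbitol-making Akr1b3 (1.30 ± 0.12), the amino acid carrier Slc38a2 (0.48 ± 0.07) and Aqp1.

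Of the MRTF-SRF targets in AT-3, 6 of 37 were higher with KCl and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 2.76e-07, but adjusted p = 0.557 with an estimated correlation). Filip1l (0.95 ± 0.11), the LIM protein Csrp1 (0.55 ± 0.08), the tropomyosin Tpm2 (0.61 ± 0.12) and Pdlim5 (0.44 ± 0.11) led them. Mrtfa itself rose (0.52 ± 0.10, adjusted p = 0.00453), from 85.9 ± 7.35 to 123 ± 7 CPM, as did the myosin light chain Myl9 (0.65 ± 0.18, adjusted p = 0.0462). Srf (0.08 ± 0.15), Mrtfb (−0.03 ± 0.17), Acta2 (0.08 ± 0.12), Actb (0.16 ± 0.13), Vcl (−0.02 ± 0.12), Cnn1 (0.63 ± 0.18), Tagln (0.39 ± 0.45), Ccn1 (0.27 ± 0.27), Ccn2 (0.90 ± 0.27) and Kcnma1 (−0.10 ± 0.82) did not pass. Among potassium channels and pumps 3 were higher and 1 lower of 31 (3 and 2 adjusted over the list alone): the pump subunit Atp1b3 (0.47 ± 0.05), Kcnk2 (2.79 ± 0.43) and Kcnj2 (1.35 ± 0.24) rose. The list's median (−0.148) and mean (−0.119) were negative and its test pointed up (camera adjusted p = 0.98). Interferon and antigen presentation genes fell, 0 higher and 5 lower of 36 (1 and 9 adjusted over the list alone, camera adjusted p = 1.46e-05, but adjusted p = 0.557 with an estimated correlation), among them Xaf1 (−1.24 ± 0.24), Gbp2 (−0.65 ± 0.14) and the peptide transporter Tap1. The metallothioneins Mt1 (−0.74 ± 0.17) and Mt2 (−1.08 ± 0.27) fell, the 2 of 6 metal-response genes that passed (camera adjusted p = 0.0153, but adjusted p = 0.195 with an estimated correlation).

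Camera called 8 further lists in AT-3 with KCl, none of which kept the call with an estimated correlation. YAP-TEAD targets had 1 of 17 higher, Crim1 (adjusted p = 0.00219, and 0.557 with an estimated correlation). Calcium handling had 3 of 40 higher, Cacnb3, Trpv6 and Cacna1c (0.0341 and 0.557). Oxidative phosphorylation had 1 of 37 lower, Sdhc (0.0362 and 0.769). G1/S (0.00971 and 0.769) and G2/M genes (0.00102 and 0.753) had 0 of 34 and 0 of 33 past the threshold. NF-kB and chemokine genes had 2 of 23 higher, Nfkb1 and Cxcl5 (0.0341 and 0.557). Adhesion genes had 4 of 43 higher, among them the integrin Itgb5 and the actin regulator Enah (0.0128 and 0.557). Mesenchymal markers had 2 of 15 higher, Snai2 and Cdh2 (0.0128 and 0.557). The remaining lists were not called. Immediate early genes had 2 of 25 higher (0.166). Calcium-NFAT and CREB targets had 0 of 20 (0.921), with a median of −0.0211 and a mean of 0.0165. ATF4 genes had 1 of 37 higher (0.921) and heat shock genes 3 of 20 (0.107). HIF1 genes had 1 of 34 higher (0.895), with a median of 0.0309 and a mean of −0.0142. ER chaperones (0 of 20, 0.107), cholesterol synthesis (0 of 25, 0.15), fatty acid synthesis (0 of 17, 0.107) and NRF2 targets (0 of 25, 0.3) had none. The same was true of aryl hydrocarbon receptor targets (0 of 5, 0.982), p53 targets (0 of 27, 0.15) and epithelial markers (0 of 19, 0.629). Collagens and matrix had Tnc, Mmp3 and Postn higher and Col16a1 lower of 39 (0.977). Markers of fibroblasts (0 of 7, 0.258), leukocytes (0 of 5, 0.98) and endothelium (0 of 6, 0.98) did not pass. In all, 455 genes were higher and 259 lower (714 in all, 86 of them at least 2-fold). The total fell to 393, 456 and 414 without DMSO replicate 1, 2 or 3 and to 417 and 414 without KCl replicate 1 or 3. Myl9 lost its call without DMSO replicate 2 or 3 or KCl replicate 1 or 3, Trpv6 without DMSO replicate 3 or KCl replicate 1, and Gfra2 without KCl replicate 2. The calls of Slc1a1, Pdlim5, Tap1, Mt1, Mt2, Cacna1c, Sdhc, Cxcl5, Cdh2, Mmp3 and Postn were also lost in at least 1 such omission.

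In E0771, KCl changed 4860 genes, 2381 higher and 2479 lower, 479 of them at least 2-fold. Ptgds, a prostaglandin D synthase, rose 17-fold (4.08 ± 0.22, adjusted p = 2.84e-11, n = 3 against 3), from 1.73 ± 0.83 to 29.8 ± 5.28 CPM. The receptors Gprc5b (3.24 ± 0.21) and Mrgprf (2.81 ± 0.23), the surface antigen Ly6c1 (2.74 ± 0.20), the glycosyltransferase Mgat3 (2.61 ± 0.20) and the transporter Slc45a3 (2.50 ± 0.19) followed. The endothelin Edn2 (−2.84 ± 0.32), the DNA methyltransferase Dnmt3b (−1.73 ± 0.13), the receptor-activity protein Ramp2 (−1.41 ± 0.15), the RNA methyltransferase Trdmt1 (−1.38 ± 0.20), Lrrc15 (−1.35 ± 0.19) and the proline-synthesis gene Pycr1 (−1.34 ± 0.15) fell most. In the hypertonic (NFAT5) list 13 of 16 members were higher and 1 lower (camera adjusted p = 4.06e-23, and adjusted p = 0.000182 with an estimated correlation), with Slc38a2 (0.91 ± 0.05), Aqp1 (1.46 ± 0.10), the chaperone Hspa4l (1.14 ± 0.07) and the taurine carrier Slc6a6 (0.51 ± 0.04).

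Mrtfa rose with KCl in E0771 too (0.35 ± 0.07, adjusted p = 9.63e-05), with Mrtfb (0.18 ± 0.06, adjusted p = 0.0263), Acta2 (0.39 ± 0.13, adjusted p = 0.0365) and Myl9 (1.48 ± 0.23, adjusted p = 6.41e-06). Srf (0.02 ± 0.06), Actb (−0.01 ± 0.04), Vcl (0.03 ± 0.06), Tagln (−0.17 ± 0.99), Cnn1 (−0.62 ± 1.07), Ccn1 (−0.16 ± 0.18) and Ccn2 (0.46 ± 0.23) did not pass. MRTF-SRF targets as a group went both ways, 7 higher and 5 lower of 36 (camera adjusted p = 0.418): Filip1l (1.18 ± 0.13) and the actin-binding Cald1 (0.37 ± 0.05) rose and Tagln2 fell (−0.30 ± 0.04). Of the ATF4 list, 16 were lower and 2 higher of 34 (camera adjusted p = 2.03e-06, but adjusted p = 0.502 with an estimated correlation), with the amino acid carriers Slc7a5 (−0.72 ± 0.04) and Slc3a2 (−0.60 ± 0.04), the asparagine synthetase Asns (−0.47 ± 0.05) and the serine pathway's Shmt2 (−0.37 ± 0.04). Glycolysis and hypoxia genes were higher, 21 against 3 lower of 35 (camera adjusted p = 2.03e-06, but adjusted p = 0.198 with an estimated correlation), including Pkm (0.36 ± 0.03), the oxygen sensor Egln1 (0.49 ± 0.04), Pfkp (0.47 ± 0.04) and Ldha (0.33 ± 0.04). Potassium channels and pumps were higher, 12 against 3 of 19 (camera adjusted p = 0.00134, but adjusted p = 0.0695 with an estimated correlation), among them the pump subunit Atp1b3 (0.57 ± 0.04) and the cotransporter Slc12a7 (0.43 ± 0.05). Fibroblast markers were also higher, 6 and 0 of 8 (camera adjusted p = 4.39e-06, and adjusted p = 0.00441 with an estimated correlation): Gsn (0.82 ± 0.05), Ly6c1, Ly6a (1.27 ± 0.16) and Pdgfrb (0.59 ± 0.08).

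Immediate early genes in E0771 with KCl split 7 higher and 10 lower of 24 (camera adjusted p = 0.284), with Ier3 (1.67 ± 0.06), Arc (1.35 ± 0.11) and the phosphatase Dusp1 (2.37 ± 0.12) up and Klf4 (−0.88 ± 0.09) down. The median (−0.038) and mean (0.219) differ in sign and the test pointed up. The other lists were not called, and are given as members higher and lower of those tested, with camera's adjusted p. YAP-TEAD targets had 8 and 2 of 16 (0.143). Calcium-NFAT and CREB targets had 3 and 7 of 17 (0.599), with a median of −0.261 and a mean of 0.0588. Calcium handling had 9 and 7 of 30 (0.229), with S100a4 up (1.98 ± 0.15). ER chaperones had 3 and 3 of 20 (0.746) and cholesterol synthesis 2 and 5 of 25 (0.599). Fatty acid synthesis had 6 and 5 of 17 (0.746), with a median of −0.021 and a mean of 0.129. Oxidative phosphorylation had 5 and 12 of 37 (0.42), NRF2 5 and 6 of 23 (0.599) and aryl hydrocarbon receptor targets 0 and 2 of 5 (0.599). Heat shock genes had 4 and 7 of 20 (0.746), with a median of −0.0352 and a mean of 0.117. The metal response had 2 and 3 of 7 (0.2), its test pointing down against a mean of 0.199. There were 3 and 8 of 26 p53 targets (0.155) and 11 and 3 of 34 G1/S genes (0.42). G2/M had 5 and 3 of 33 (0.943), with a median of −0.00903 and a mean of 0.00887. NF-kB genes had 7 and 2 of 19 (0.0716), interferon genes 10 and 2 of 37 (0.229), collagens 12 and 3 of 32 (0.0533) and adhesion genes 16 and 7 of 41 (0.0866). Epithelial markers had 1 and 2 of 11 (0.746), with a median of −0.0503 and a mean of 0.0399. Mesenchymal markers had 4 and 3 of 14 (0.746), with a median of −0.0816 and a mean of 0.0126. Leukocyte markers had 1 and 1 of 5 (0.746), and the endothelial list had 4 tested members and was not tested. Within these, the chaperone Cryab (1.33 ± 0.08) rose, and Mt1 (−0.75 ± 0.06) and Mt2 (−1.31 ± 0.15) fell. Adjusted over the list alone, counts moved by 1 member in 7 lists (YAP-TEAD, calcium handling, cholesterol synthesis, NRF2, p53, collagens and leukocytes) and by 0 in the others. The calls of Mrtfb (without DMSO replicate 1 or 2 or KCl replicate 2) and Acta2 (without any 1 DMSO replicate or KCl replicate 2 or 3) were lost. The total stayed between 4045 and 4428.

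Between the lines, the effect of KCl differed for 1458 of 15969 genes, 657 more positive in E0771 and 801 more negative. Which direction held more genes turned with the setting: 739 and 712 with DESeq2 size factors, 965 and 930 with DESeq2, 651 and 568 without a filter, 883 and 696 with a filter of 1 CPM, 799 and 680 with halved counts and 997 and 833 with only the libraries compared. It turned too without AT-3 DMSO replicate 1 or 3, E0771 DMSO replicate 1, 2 or 3, any 1 AT-3 KCl replicate and E0771 KCl replicate 1 or 2. Gprc5b (3.20 ± 0.35), Slc45a3 (2.73 ± 0.27) and the actin-oxidizing enzyme Mical2 (2.29 ± 0.14) had the more positive change in E0771. Aqp1 (−2.73 ± 0.57), Serpinb9 (−1.93 ± 0.23) and Klf4 (−1.49 ± 0.31) had it in AT-3. ATF4 genes differed (0 higher and 11 lower of 37, 0 and 13 adjusted over the list alone, camera adjusted p = 1.2e-05, but adjusted p = 0.712 with an estimated correlation), with Slc7a5 at −0.45 ± 0.11. HIF1 genes differed the other way (6 and 0 of 35, camera adjusted p = 0.000506, but adjusted p = 0.712 with an estimated correlation), as did interferon genes (7 and 1 of 37, camera adjusted p = 1.2e-05, but adjusted p = 0.291 with an estimated correlation), with Tapbp (0.97 ± 0.11) and Ddx58 (0.93 ± 0.14). MRTF-SRF targets did not differ as a list (1 and 3 of 37, 0.153), though Tpm2 did (−0.90 ± 0.14). For the 12278 genes tested in both lines the log2 changes correlated at 0.26. In both lines 199 genes were higher (64.3 if the calls were independent), 137 were lower (46) and 34 were opposite.

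NS11021 at 10 µM changed 11 genes in AT-3, 10 higher and 1 lower, and 4 of the 10 belong to the amino acid stress response driven by ATF4. Slc7a5, an amino acid carrier, rose 1.63-fold (0.70 ± 0.10, adjusted p = 0.005, n = 3 against 3), from 207 ± 2.53 to 336 ± 10.8 CPM. The alcohol dehydrogenase Adh7 (1.28 ± 0.22), the mitochondrial enzyme Pck2 (0.70 ± 0.10), the ER protein Fkbp11 (0.61 ± 0.11), the proline-synthesis enzyme Aldh18a1 (0.56 ± 0.08) and the ER stress gene Herpud1 (0.47 ± 0.08) also rose, and the transcription inhibitor Id3 fell (−0.41 ± 0.07). The ATF4 list had 4 of 37 members higher over all genes, Shmt2 (0.37 ± 0.07) being the fourth, and 29 adjusted over the list alone (camera adjusted p = 3.39e-50, and adjusted p = 0.0291 with an estimated correlation). HIF1 genes had 0 of 34 past the threshold and 23 higher adjusted over the list alone (camera adjusted p = 2.79e-22, but adjusted p = 0.0698 with an estimated correlation), but the list's mean log2 level, centred on the line, was 0.07, 0.67 and 0.23 in the 3 libraries (−0.09, −0.08 and −0.16 in DMSO), highest in NS11021 replicate 2. With KCl the 3 NS11021 libraries had −0.02, 0.50 and 0.09, again highest in replicate 2. Without NS11021 replicate 2 the list's median went from 0.34 to 0.23. NF-kB and chemokine genes (0 of 23, and 4 adjusted over the list alone, camera adjusted p = 1e-08, and adjusted p = 0.0291 with an estimated correlation), aryl hydrocarbon receptor targets (0 of 5, and 3; 1.63e-06 and 0.0291) and epithelial markers (0 of 19, and 1; 0.000397 and 0.031) were higher as lists.

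None of the 12 index genes passed with NS11021 in AT-3: Srf 0.10 ± 0.15, Mrtfa 0.00 ± 0.10, Acta2 0.34 ± 0.12, Myl9 0.41 ± 0.18, Cnn1 0.44 ± 0.18, Ccn2 0.30 ± 0.27. MRTF-SRF targets were higher by camera with 0 members past the threshold (adjusted p = 8.42e-05, but adjusted p = 0.704 with an estimated correlation). The same holds for immediate early genes (camera adjusted p = 1.53e-06, but adjusted p = 0.542 with an estimated correlation). ER chaperones were higher with 1 member past the threshold, Herpud1 (8.42e-05 and 0.0698), while cholesterol synthesis genes were lower (8.42e-05 and 0.705). At unadjusted p below 0.05 there were 1129 genes, DESeq2 called 70, and 83 passed with only the libraries of the 2 groups compared. Every named gene lost its call without at least 1 library: the total was 2 without DMSO replicate 2, 0 without DMSO replicate 3, and 7, 3 and 4 without NS11021 replicate 1, 2 or 3, and Slc7a5 was lost without DMSO replicate 2 or 3.

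In E0771 the same dose of NS11021 changed 3515 genes, 1715 higher and 1800 lower, 157 of them at least 2-fold. The stress cytokine Gdf15 (1.71 ± 0.29, adjusted p = 0.000815), the lysosomal glycoprotein Cd68 (1.55 ± 0.13), the cholesterol esterifier Soat2 (1.40 ± 0.45), the stress gene Gadd45a (1.35 ± 0.28), the EGF-receptor ligand Areg (1.30 ± 0.21) and Disp2 (1.23 ± 0.26) rose most. Txnip, a glucose-sensing inhibitor of glucose uptake, fell 5.11-fold (−2.35 ± 0.19, adjusted p = 3.59e-10), followed by the connexin Gja4 (−1.23 ± 0.14), the kinase Dmpk (−1.19 ± 0.19), Mrgprf (−1.10 ± 0.28), AC160336.1 (−1.07 ± 0.16) and the iodide carrier Slc5a5 (−1.03 ± 0.21). Acta2, smooth muscle actin, rose 1.76-fold (0.81 ± 0.13, adjusted p = 0.000613), from 87.8 ± 1.36 to 154 ± 4.42 CPM, with Vcl (0.20 ± 0.06, adjusted p = 0.011) and Ccn1 (0.63 ± 0.18, adjusted p = 0.0176). Srf (0.04 ± 0.06), Mrtfa (0.12 ± 0.07), Myl9 (0.58 ± 0.24) and Ccn2 (−0.24 ± 0.23) did not pass. Of MRTF-SRF targets 10 were higher and 1 lower of 36 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00306, but adjusted p = 0.482 with an estimated correlation), with Pdlim5 (0.43 ± 0.06) and Itga5 (0.21 ± 0.05).

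The ATF4 list was higher in E0771 with NS11021 as well, 21 and 0 of 34 (25 and 0 adjusted over the list alone, camera adjusted p = 1.27e-11, but adjusted p = 0.456 with an estimated correlation): Asns (0.30 ± 0.05), Aldh18a1 (0.46 ± 0.06), the seryl-tRNA synthetase Sars (0.42 ± 0.06) and Pycr1 (0.87 ± 0.14). HIF1 genes went down, 3 higher and 19 lower of 35 (4 and 19 adjusted over the list alone, camera adjusted p = 8.77e-10, but adjusted p = 0.24 with an estimated correlation), with the phosphofructokinase Pfkl (−0.54 ± 0.04), Ak4 (−0.68 ± 0.06), Egln1 (−0.49 ± 0.04) and Ldha (−0.37 ± 0.04). G1/S genes fell, 0 and 21 of 34 (0 and 23 adjusted over the list alone, camera adjusted p = 2.78e-10, but adjusted p = 0.456 with an estimated correlation), with the licensing factor Cdc6 (−0.67 ± 0.06) and the cyclin Ccne2 (−0.55 ± 0.07). ER chaperones (2 and 8 of 20, camera adjusted p = 0.00985, but adjusted p = 0.456 with an estimated correlation, Hspa5 −0.32 ± 0.04) and heat shock genes (0 and 9 of 20, camera adjusted p = 0.00306, but adjusted p = 0.519 with an estimated correlation, Dnajb1 −0.58 ± 0.07) fell, and p53 targets rose (8 and 2 of 26, camera adjusted p = 0.00985, but adjusted p = 0.456 with an estimated correlation, Rrm2b 0.79 ± 0.10). Cholesterol synthesis had 6 of 25 lower (camera adjusted p = 0.037, but adjusted p = 0.773 with an estimated correlation). The total ranged from 2553 to 2972 with 1 library left out. Soat2 lost its call whichever of the 6 libraries was left out and Ccn1 without DMSO replicate 1 or 3 or NS11021 replicate 1 or 2.

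The effect of NS11021 differed between lines for 637 genes, 238 more positive in E0771 and 399 more negative. That lean was not kept with a filter of 1 CPM (372 and 340), without a filter (250 and 217), or without AT-3 DMSO replicate 1 (308 and 244), AT-3 NS11021 replicate 2 (251 and 232) or E0771 NS11021 replicate 1 (260 and 227). Gdf15 (1.48 ± 0.37), Cd68 (1.44 ± 0.39) and Prune2 (1.21 ± 0.29) were among the first group, and the hypoxia genes Ak4 (−2.36 ± 0.37), Bnip3 (−2.22 ± 0.42) and Egln3 (−1.73 ± 0.43) led the other. The HIF1 list differed with 0 higher and 23 lower of 35 (1 and 24 adjusted over the list alone, camera adjusted p = 1.03e-24, and adjusted p = 0.0409 with an estimated correlation, lost in 7 of 12 omissions of 1 library), with Egln1 (−0.88 ± 0.09), Pgam1 (−0.65 ± 0.09) and Pfkl (−0.91 ± 0.12). ER chaperones differed in the same direction (0 and 8 of 20, 0 and 10 adjusted over the list alone, camera adjusted p = 4.39e-08, and adjusted p = 0.0284 with an estimated correlation, also lost in 7 of 12), with Hspa5 (−0.55 ± 0.07) and Herpud1 (−0.54 ± 0.11). Of the 11 genes called in AT-3, 6 were also higher in E0771 (1.33 if independent), 1 lower (0.145) and 0 opposite, and the log2 changes correlated at 0.109 (0.19 with a filter of 1 CPM). The total fell to 387 without AT-3 DMSO replicate 2, 417 and 394 without AT-3 NS11021 replicate 1 or 3, 344 and 356 without E0771 DMSO replicate 1 or 3 and 270 without E0771 NS11021 replicate 2. Gdf15, Cd68, Prune2 and Egln3 were lost in at least 1 of these.

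BMS204352 raised immediate early and stress genes in AT-3. The collagen VI genes Col6a2 (3.44 ± 0.82, 10.9-fold, adjusted p = 0.0353) and Col6a1 (8.02-fold), the calcium-responsive factor Nfatc2 (3.36 ± 0.83), the AP-1 factors Fosb (3.12 ± 0.66) and Fos (2.70 ± 0.58) and Areg (2.64 ± 0.57) had the largest rises, all n = 3 against 3. The metalloreductase Steap4 (−2.09 ± 0.35), the ETS factor Erg (−1.75 ± 0.42), the matrix protein Ogn (−1.65 ± 0.25), the protease Adamts5 (−1.50 ± 0.29), Gfra2 (−1.37 ± 0.24) and Chodl (−1.35 ± 0.31) fell most. Of immediate early genes 15 of 25 were higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 6.78e-24, but adjusted p = 0.0911 with an estimated correlation), among them Ier2 (0.70 ± 0.09), Egr2 (1.45 ± 0.23), Junb (0.56 ± 0.10) and Ier3 (1.22 ± 0.20). Calcium-NFAT and CREB targets were higher too, 10 and 0 of 20 (16 and 0 adjusted over the list alone, camera adjusted p = 1.26e-12, but adjusted p = 0.0911 with an estimated correlation): the ERK phosphatase Dusp6 (0.96 ± 0.18), Areg, Sik1 and the G-protein regulator Rgs2 (1.77 ± 0.40). So was the ATF4 list, 24 and 0 of 37 (32 and 0 adjusted over the list alone, camera adjusted p = 4.14e-29, but adjusted p = 0.0911 with an estimated correlation), with Aldh18a1 (0.50 ± 0.08), Sars (0.56 ± 0.09), Slc7a5 (0.62 ± 0.10) and Pck2 (0.59 ± 0.10).

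MRTF-SRF targets were not called as a list with BMS204352 in AT-3 (0 higher and 1 lower of 37; median 0.0157, mean −0.0193, test down, camera adjusted p = 0.866). Without the replicate 3 libraries the list was called lower (median −0.07, camera adjusted p = 0.0453) with 0 members past the threshold. With all libraries none of the index genes passed: Srf 0.00 ± 0.15, Mrtfa −0.17 ± 0.10, Acta2 0.02 ± 0.12, Myl9 −0.49 ± 0.18, Cnn1 −0.45 ± 0.19, Ccn2 −0.11 ± 0.27. Kcnn4 rose (1.34 ± 0.22) among potassium channels (4 higher and 1 lower of 31, camera adjusted p = 0.0304, but adjusted p = 0.223 with an estimated correlation and 0.0866 without the replicate 3 libraries), and the calcium channel Trpv6 rose (0.70 ± 0.10; list 6 and 1 of 40, camera adjusted p = 0.00319, but adjusted p = 0.179 with an estimated correlation). Cell cycle genes leaned down, G2/M with 2 of 33 lower and 25 adjusted over the list alone (camera adjusted p = 5.45e-13, but adjusted p = 0.223 with an estimated correlation) and G1/S with 3 of 34 lower and 4 adjusted over the list alone (camera adjusted p = 8.47e-07, but adjusted p = 0.382 with an estimated correlation). Without the replicate 3 libraries 1 and 0 members were lower (camera adjusted p = 2.1e-07 and 0.0349). Cholesterol synthesis was lower by camera with 0 of 25 past the threshold (camera adjusted p = 1.48e-10, but adjusted p = 0.223 with an estimated correlation). NRF2 targets had 4 of 25 higher (7 adjusted over the list alone, camera adjusted p = 0.00106, but adjusted p = 0.0911 with an estimated correlation), with the cystine carrier Slc7a11 (1.24 ± 0.27).

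In all BMS204352 changed 779 genes in AT-3, 484 higher and 295 lower, 184 of them at least 2-fold, and 449 (305 and 144) without the replicate 3 libraries. Immediate early genes then had 11 higher and ATF4 21. The total fell to 285, 337 and 146 without DMSO replicate 1, 2 or 3 and 220 without BMS204352 replicate 3, rose to 1743 without BMS204352 replicate 1, and was 10 when only the 6 libraries compared were fitted. Col6a2, Col6a1, Nfatc2, Fosb and Fos lost their calls without any 1 DMSO replicate or without BMS204352 replicate 3. Areg and Rgs2 lost theirs without any 1 DMSO replicate, and Dusp6 and Adamts5 without DMSO replicate 3. Steap4, Ogn, Gfra2, Ier2, Egr2, Junb, Ier3, Kcnn4, Slc7a5 and Pck2 kept theirs with each library left out.

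In E0771 BMS204352 changed 3028 genes, 1516 higher and 1512 lower, 165 at least 2-fold (2593 without the replicate 3 libraries). The carbonic anhydrase Car6 had the largest rise (4.75 ± 0.93, adjusted p = 0.00291), but its libraries read 16.1, 9.12 and 110 CPM against 1.67 ± 0.173 in DMSO. The keratinocyte gene Cdsn (2.34 ± 0.57), Chchd10 (1.66 ± 0.44), the stress factor Ddit3 (1.58 ± 0.39), Gdf15 (1.52 ± 0.29) and Soat2 (1.50 ± 0.45) followed. Ccn2, a target shared by SRF and YAP, fell 3.33-fold (−1.74 ± 0.25, adjusted p = 2.59e-05), from 6.05 ± 0.812 to 1.84 ± 1.01 CPM, with the calcium channel Cacna1a (−1.73 ± 0.19), Slc5a5 (−1.66 ± 0.22), the lipogenic Thrsp (−1.53 ± 0.28), Txnip (−1.25 ± 0.17) and Gja4 (−1.22 ± 0.14). Actb fell (−0.21 ± 0.04, adjusted p = 0.000207) and Mrtfa rose (0.22 ± 0.07, adjusted p = 0.0151). Acta2 (−0.40 ± 0.14, adjusted p = 0.0533), Srf (−0.15 ± 0.06), Vcl (0.02 ± 0.06), Myl9 (−0.37 ± 0.25) and Ccn1 (−0.04 ± 0.18) did not pass. MRTF-SRF targets went both ways (4 higher and 7 lower of 36, camera adjusted p = 0.259). YAP-TEAD targets had 3 higher and 6 lower of 16 (3 and 7 adjusted over the list alone, camera adjusted p = 0.00342, but adjusted p = 0.459 with an estimated correlation), with Amotl2 (−1.08 ± 0.08) and Ajuba (−0.57 ± 0.07) down and the ectonucleotidase Nt5e up (0.49 ± 0.08).

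ATF4 genes rose in E0771 with BMS204352, 24 and 0 of 34 (28 and 0 adjusted over the list alone, camera adjusted p = 1.18e-16, but adjusted p = 0.459 with an estimated correlation), led by Asns, Aldh18a1, Gars and Pycr1 (0.92 ± 0.14). G1/S genes fell, 0 and 21 of 34 (0 and 23 adjusted over the list alone, camera adjusted p = 1.05e-10, but adjusted p = 0.459 with an estimated correlation, Cdc6 −0.60 ± 0.06), with G2/M genes (0 and 13 of 33, 1 and 8 without the replicate 3 libraries, camera adjusted p = 3.59e-05, but adjusted p = 0.645 with an estimated correlation, Kif23 −0.28 ± 0.04), cholesterol synthesis (0 and 9 of 25, camera adjusted p = 0.00305, but adjusted p = 0.645 with an estimated correlation) and heat shock genes (0 and 9 of 20, camera adjusted p = 0.00342, but adjusted p = 0.615 with an estimated correlation). HIF1 genes were mixed (7 and 9 of 35, 0.384). Mrtfa lost its call without DMSO replicate 1 or BMS204352 replicate 3, Chchd10 without DMSO replicate 1 or 2, and Soat2 without any 1 DMSO replicate or BMS204352 replicate 3.

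The effect of BMS204352 differed between lines for 800 genes, 302 more positive in E0771 and 498 more negative (570 without the replicate 3 libraries). Prune2 (1.55 ± 0.29), Chchd10 (1.46 ± 0.42) and Dtna (1.42 ± 0.25) lay on the E0771 side and Nfatc2 (−4.02 ± 0.83), Col6a2 (−3.58 ± 0.78) and Col6a1 (−3.17 ± 0.70) on the AT-3 side. Immediate early genes responded less in E0771, 0 and 8 of 25 (0 and 14 adjusted over the list alone, camera adjusted p = 7.53e-11, but adjusted p = 0.465 with an estimated correlation), with Ier2 at −0.84 ± 0.10. Ccn2 differed as well (−1.65 ± 0.43, adjusted p = 0.0217), a call lost without AT-3 DMSO replicate 2 or BMS204352 replicate 3, without E0771 DMSO replicate 1 or BMS204352 replicate 3, and without the replicate 3 libraries together. Both lines shared 124 genes higher (49 if independent) and 47 lower (23.5), with 44 opposite and a correlation of 0.131 (0.227 with a filter of 1 CPM). Without AT-3 BMS204352 replicate 1 the total was 1205.

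**Figure D2:**
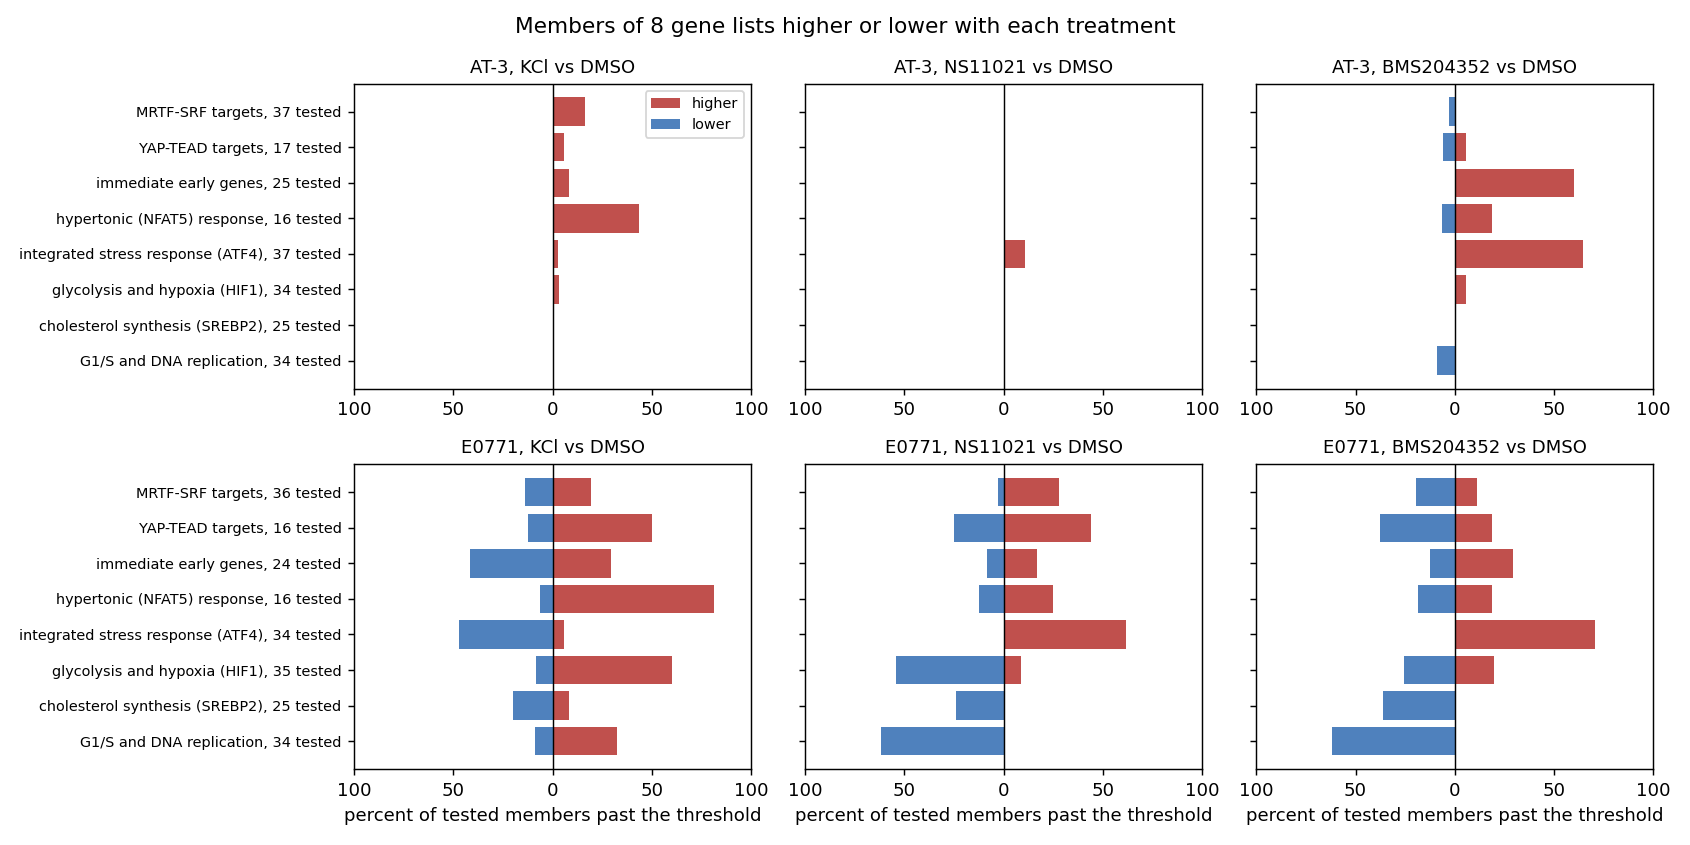
Percent of tested members higher (right) and lower (left) at adjusted p below 0.05 in 8 gene lists, for KCl, NS11021 and BMS204352 against DMSO in each line. The NFAT5 list rose with KCl in both lines, and the ATF4 list rose with both compounds, a call that only NS11021 in AT-3 kept with an estimated correlation (adjusted p = 0.0291, against 0.0911 for BMS204352 in AT-3 and 0.456 and 0.459 for NS11021 and BMS204352 in E0771).

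In raised potassium, NS11021 changed 3 genes in AT-3: Pck2 (0.61 ± 0.10), Slc7a5 (0.61 ± 0.10) and the cytokine Lif (0.49 ± 0.08), each with adjusted p = 0.0342. DESeq2 called 14, 23 passed with only the libraries of the 2 groups compared, and 549 genes had an unadjusted p below 0.05. The ATF4 list had 2 of 37 higher (25 adjusted over the list alone, camera adjusted p = 4e-52, but adjusted p = 0.0589 with an estimated correlation). All 3 calls ended without any 1 KCl replicate or without KCl+NS11021 replicate 1 or 2, when the total was 0. BMS204352 added to KCl changed 183 genes in AT-3 (108 higher, 75 lower; 273 without the replicate 3 libraries). Egr4 (1.29 ± 0.31), Egr1 (1.18 ± 0.18) and Egr2 (1.14 ± 0.23), early growth response factors, rose most, and Ogn (−1.73 ± 0.25), the phospholipase Plce1 (−1.28 ± 0.29) and Serpinb9 (−1.26 ± 0.17) fell most. Calponin, Cnn1, fell (−0.90 ± 0.18, adjusted p = 0.0244), with the tropomyosin Tpm1 (−0.46 ± 0.08), the MRTF-SRF list having 0 higher and 2 lower of 37 (0 and 5 adjusted over the list alone, camera adjusted p = 1.41e-05, but adjusted p = 0.461 with an estimated correlation). Immediate early genes had 3 of 25 higher (12 adjusted over the list alone, camera adjusted p = 1.55e-15, but adjusted p = 0.295 with an estimated correlation) and the ATF4 list 9 of 37 (27 adjusted over the list alone, camera adjusted p = 8.78e-25, but adjusted p = 0.295 with an estimated correlation). Without the replicate 3 libraries these were 9 and 14. The total fell to 38, 51 and 20 without KCl replicate 1, 2 or 3 and to 41 and 21 without KCl+BMS204352 replicate 2 or 3. Cnn1 and Tpm1 were lost without KCl replicate 1 or 3 or KCl+BMS204352 replicate 2 or 3, and Egr1 without KCl replicate 3.

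In E0771, NS11021 added to KCl changed 2304 genes (1281 higher, 1023 lower). The glycolipid enzyme A4galt (1.63 ± 0.20), Disp2 (1.62 ± 0.28) and Areg (1.30 ± 0.22) rose most and the linker histone Hist1h1c (−0.93 ± 0.12), Cacna1a (−0.88 ± 0.17) and Fam13b (−0.78 ± 0.10) fell most. None of the index genes passed (Acta2 0.41 ± 0.13, adjusted p = 0.051). Cholesterol synthesis genes fell, 0 and 14 of 25 (0 and 19 adjusted over the list alone, camera adjusted p = 3.58e-13, but adjusted p = 0.304 with an estimated correlation), as did G1/S genes (0 and 23 of 34, camera adjusted p = 2.25e-14, but adjusted p = 0.304 with an estimated correlation). BMS204352 added to KCl changed 2663 genes (1316 higher, 1347 lower; 2460 without the replicate 3 libraries, and 1759 without KCl+BMS204352 replicate 3 alone). Disp2 (1.67 ± 0.28), Edn2 (1.46 ± 0.33) and Pycr1 (1.36 ± 0.15) rose most and Ccn2 (−2.14 ± 0.25, adjusted p = 1.29e-06), Cacna1a (−1.56 ± 0.18) and the caveolar Cavin2 (−1.43 ± 0.22) fell most. MRTF-SRF targets fell, 2 higher and 16 lower of 36 (2 and 17 adjusted over the list alone, camera adjusted p = 1.71e-08, but adjusted p = 0.121 with an estimated correlation), including Myl9 (−1.81 ± 0.24, adjusted p = 2.18e-06), Tpm4 (−0.35 ± 0.05) and Actb (−0.24 ± 0.04, adjusted p = 4.5e-05), and so did Srf (−0.26 ± 0.06, adjusted p = 0.00227), Acta2 (−0.89 ± 0.14, adjusted p = 0.000495) and Ccn1 (−1.11 ± 0.19, adjusted p = 0.00101). YAP-TEAD targets fell too, 2 and 9 of 16 (2 and 10 adjusted over the list alone, camera adjusted p = 1.04e-08, but adjusted p = 0.0502 with an estimated correlation, Ajuba −0.73 ± 0.07), and NFAT5 genes, 0 and 8 of 16 (1 and 8 adjusted over the list alone, camera adjusted p = 7.16e-06, but adjusted p = 0.0502 with an estimated correlation, Akr1b3 −0.86 ± 0.09). Fibroblast markers moved with these lists, 1 higher and 3 lower of 8 (camera adjusted p = 0.0243, but adjusted p = 0.14 with an estimated correlation), and 0 and 4 without the replicate 3 libraries (0.00298). The mitochondrial share of the KCl+BMS204352 libraries was 0.789 to 1.03%, against 0.678 to 0.739% in KCl.

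Whether KCl changes the effect of a compound was tested as an interaction. In AT-3 edgeR's quasi-likelihood test called 0 genes for either compound, DESeq2 also called 0 and 0, and 299 and 533 genes had an unadjusted p below 0.05. Without the replicate 3 libraries the count for BMS204352 was 6. In E0771, 29 genes interacted for NS11021, 26 higher and 3 lower, with Txnip (1.83 ± 0.25), Gja4 (0.85 ± 0.18) and Prr5 (0.79 ± 0.17) on 1 side and Ampd3 (−0.58 ± 0.10) and Capg (−0.27 ± 0.05) on the other. For BMS204352 there were 217 (76 higher, 141 lower; 373 without the replicate 3 libraries), with Edn2 (2.11 ± 0.43), Slc5a5 (1.26 ± 0.30), the erythropoietin receptor Epor (1.13 ± 0.26), Dusp1 (−1.19 ± 0.16), the cytokine Il34 (−1.16 ± 0.22) and Ampd3 (−1.10 ± 0.10). The hypertonic response to KCl was smaller with BMS204352: 5 of 16 NFAT5 genes had a negative interaction and 0 a positive one (camera adjusted p = 3.05e-09, and adjusted p = 0.0116 with an estimated correlation), with the aldo-keto reductases Akr1b8 (−0.99 ± 0.14) and Akr1b3 (−0.90 ± 0.12), Hspa4l and Aqp1 (−0.66 ± 0.13). Myl9 interacted as well (−1.45 ± 0.34, adjusted p = 0.0259). Without the replicate 3 libraries the MRTF-SRF list had a negative interaction of KCl and BMS204352 at the preset correlation. It had 0 higher and 8 lower of 36 in E0771 (median −0.17, camera adjusted p = 1.2e-08). In AT-3 it had 0 and 0 of 37 (median −0.18, camera adjusted p = 0.000101). That setting was not run with an estimated correlation, and the negative interaction was not particular to this list. In AT-3 calcium-NFAT and CREB targets and adhesion genes had it too (camera adjusted p = 0.000534 each), while oxidative phosphorylation had a positive one (0.0458). So did YAP-TEAD targets (0.00019) and adhesion genes (1.84e-05) have a negative one in E0771. Fibroblast markers had 0 of 8 past the threshold (camera adjusted p = 0.063), and without the replicate 3 libraries 0 higher and 3 lower (0.0142). The mitochondrial share was 0.789 to 1.03% in the KCl+BMS204352 libraries of this contrast. The count for NS11021 was 12, 19 and 10 without DMSO replicate 1, 2 or 3, 12, 6 and 14 without KCl replicates, 16 and 10 without NS11021 replicate 1 or 2 and 18, 11 and 13 without KCl+NS11021 replicates. For BMS204352 it was 122, 135 and 136 without DMSO replicates, 91 and 83 without KCl replicate 1 or 2, and 106 and 133 without KCl+BMS204352 replicate 1 or 2. Gja4, Prr5, Capg, Edn2, Slc5a5, Epor and Myl9 lost their calls in at least 1 of these.

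Set against each other at the same dose and time in AT-3, the compounds differed in 434 genes, 229 higher with NS11021 and 205 lower (268 without the replicate 3 libraries). Egln3 (2.02 ± 0.46), Bnip3 (2.01 ± 0.41) and Steap4 (4.01-fold) were higher with NS11021 and Col6a2 (−3.40 ± 0.82), Col6a1 (−2.99 ± 0.73) and the nuclear receptor Nr4a3 (−1.64 ± 0.34) lower. Myl9 (0.90 ± 0.18, 95% interval 0.52 to 1.28, adjusted p = 0.015) and Cnn1 (0.89 ± 0.19, adjusted p = 0.0149) were higher with NS11021, with MRTF-SRF targets 3 and 0 of 37 (4 and 0 adjusted over the list alone, camera adjusted p = 0.00375, but adjusted p = 0.573 with an estimated correlation). Slc7a5 differed by 0.08 (−0.12 to 0.29) and Srf by 0.10 (−0.22 to 0.42). HIF1 genes were higher with NS11021 (10 and 0 of 34, 16 and 1 adjusted over the list alone, camera adjusted p = 5.35e-11, but adjusted p = 0.312 with an estimated correlation), though with 2 past the threshold without the replicate 3 libraries. Immediate early genes were lower (0 and 3 of 25, 1 and 16 adjusted over the list alone, camera adjusted p = 1.34e-12, but adjusted p = 0.312 with an estimated correlation), with 0 and 8 past the threshold without the replicate 3 libraries. With KCl 67 genes differed (106 without the replicate 3 libraries), Ogn (1.72 ± 0.25), Gabrp (1.68 ± 0.28) and the retinoic acid hydroxylase Cyp26b1 (1.12 ± 0.10) higher with NS11021 and Atp6v0a4 (−1.13 ± 0.20), Slco4a1 (−1.01 ± 0.20) and Gal3st1 (−0.94 ± 0.21) lower. Cnn1 was higher again (0.90 ± 0.18, adjusted p = 0.0353). Without KCl the total was 169, 218 and 79 without NS11021 replicate 1, 2 or 3, 1070 and 140 without BMS204352 replicate 1 or 3, and 14 with only the 6 libraries compared. With KCl it was 9, 21 and 5 without KCl+NS11021 replicates and 10 and 4 without KCl+BMS204352 replicate 2 or 3. Myl9 and Cnn1 lost their calls without NS11021 replicate 1 or 3, and Cnn1 in the KCl arm without any 1 KCl+NS11021 replicate.

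In E0771 actin and MRTF-SRF genes stood higher with NS11021 than with BMS204352. Without KCl 235 genes differed (151 higher with NS11021, 84 lower; 314 without the replicate 3 libraries): Ccn2 (1.49 ± 0.26, 95% interval 0.97 to 2.02), Acta2 (1.21 ± 0.14, 0.92 to 1.50) and Ly6c1 (1.13 ± 0.21) were higher with NS11021 and Txnip (−1.10 ± 0.19), the arrestin Arrb1 (−0.76 ± 0.11) and Bnip3 (−0.62 ± 0.10) lower. Acta2 stood at 154 ± 4.42 CPM with NS11021 and 66.8 ± 15.4 with BMS204352. Of the MRTF-SRF list 9 of 36 were higher with NS11021 and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 9.5e-18, and adjusted p = 0.0101 with an estimated correlation), with Actb (0.22 ± 0.04, adjusted p = 0.00148) and Myl9 (0.94 ± 0.24, adjusted p = 0.0378). YAP-TEAD targets had 4 and 0 of 16 (1.01e-10 and 0.0101), with Amotl2 (0.57 ± 0.08). HIF1 genes were lower with NS11021, 0 and 12 of 35 (1 and 21 adjusted over the list alone, camera adjusted p = 4.59e-21, and adjusted p = 0.0101 with an estimated correlation), including P4ha2 (−0.40 ± 0.06) and Pfkl (−0.27 ± 0.04). The total was 109, 156 and 120 without NS11021 replicate 1, 2 or 3, 406 without BMS204352 replicate 2, and 0 with only the 6 libraries compared. Myl9 was lost without NS11021 replicate 1 or BMS204352 replicate 2 or 3.

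The same direction held in E0771 with KCl, where 661 genes differed (523 higher, 138 lower; 1081 without the replicate 3 libraries). Ccn2 (1.62 ± 0.25), Ptgds (1.53 ± 0.17) and Ccn5 (1.39 ± 0.14) were higher with NS11021 and Mboat1 (−0.81 ± 0.19), Hist1h1c (−0.73 ± 0.12) and mt-Nd4l (−0.64 ± 0.18) lower. Srf (0.25 ± 0.06, 95% interval 0.12 to 0.37, adjusted p = 0.0135), Acta2 (1.30 ± 0.14, 1.01 to 1.60), Myl9 (1.36 ± 0.24, 0.87 to 1.85), Actb (0.22 ± 0.04), Vcl (0.21 ± 0.06, adjusted p = 0.0312) and Ccn1 (0.80 ± 0.19, adjusted p = 0.0283) were all higher with NS11021, and Mrtfa (0.06 ± 0.07) was not. MRTF-SRF targets had 15 and 0 of 36 (20 and 0 adjusted over the list alone, camera adjusted p = 8.46e-17, and adjusted p = 0.011 with an estimated correlation), YAP-TEAD targets 9 and 0 of 16 (4.51e-14 and 0.00366) and NFAT5 genes 7 and 0 of 16 (4.56e-15 and 0.00131; Ccl2 0.87 ± 0.11). Fibroblast markers were also higher, 4 and 0 of 8 (0.000215 and 0.011), with Ly6c1 and Ly6a. The mitochondrial share differed in this contrast too, at 0.725 to 0.750% with KCl+NS11021 and 0.789 to 1.03% with KCl+BMS204352. Slc7a5 was lower with NS11021 here (−0.23, 95% interval −0.32 to −0.15, adjusted p = 0.000444). The total was 411, 390 and 414 without KCl+NS11021 replicates and 356 and 434 without KCl+BMS204352 replicate 1 or 2. Srf was lost without KCl+NS11021 replicate 1 or KCl+BMS204352 replicate 2 or 3, and Vcl and Ccn1 without KCl+NS11021 replicate 1 or 2 or KCl+BMS204352 replicate 3.

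**Figure D3:**
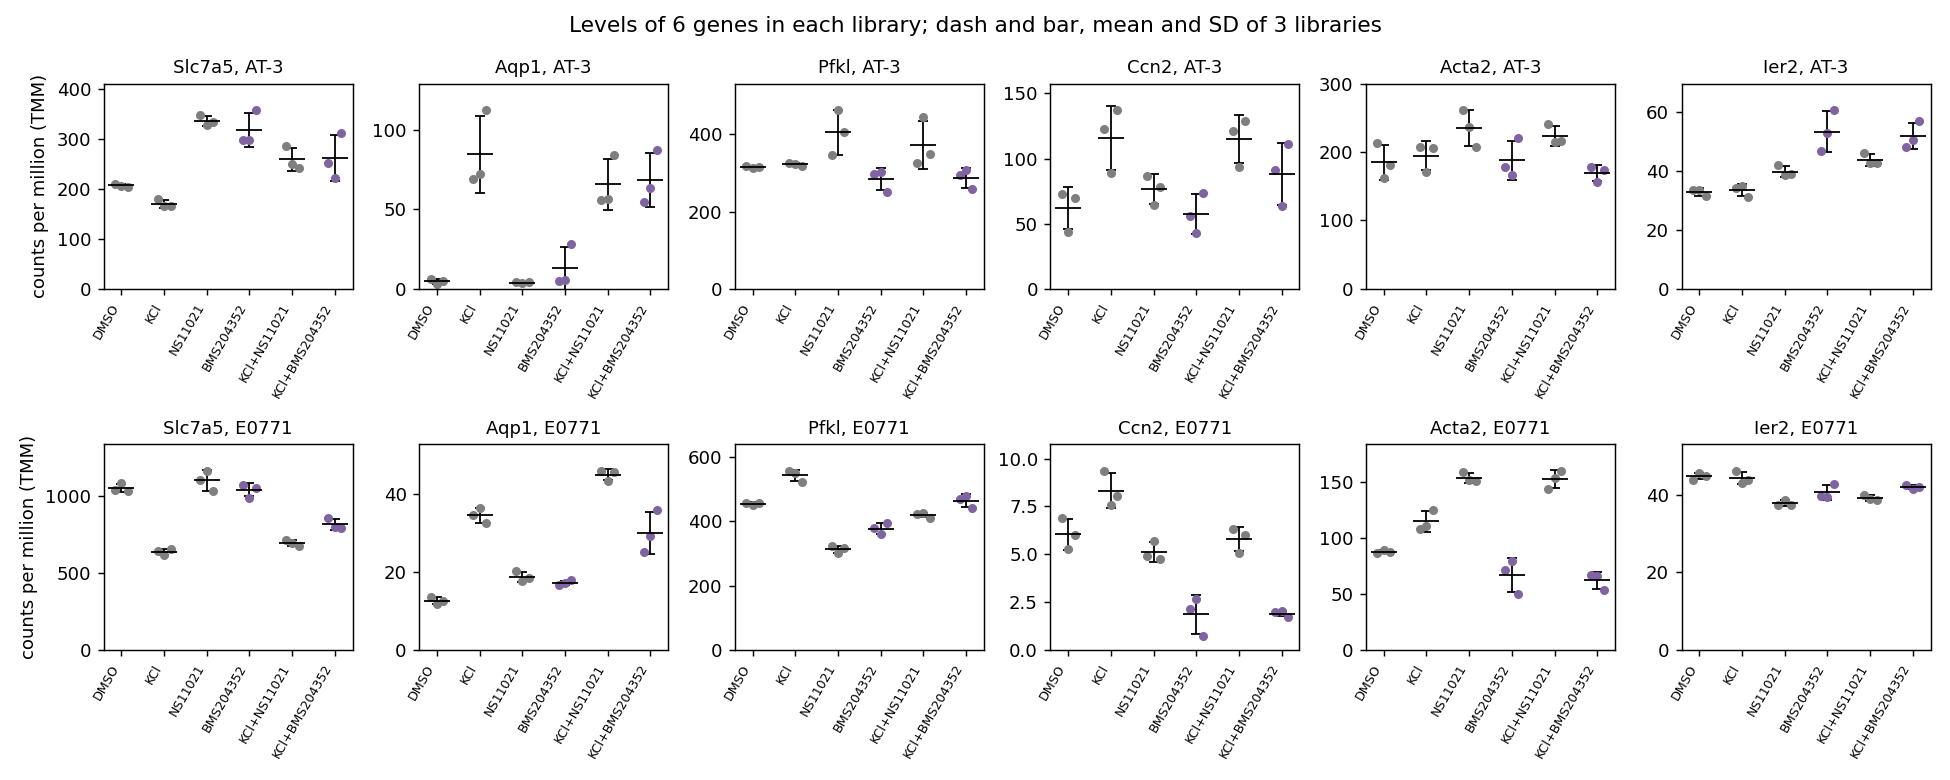
CPM of Slc7a5, Aqp1, Pfkl, Ccn2, Acta2 and Ier2 in each library, AT-3 above and E0771 below, with the mean and SD of 3 libraries per treatment. Acta2 in E0771 was 154 ± 4.42 CPM with NS11021 and 66.8 ± 15.4 with BMS204352.

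The compounds' changes against DMSO correlated at 0.696 in E0771, against 0.508 in simulated data where only the DMSO libraries were shared, and the covariance was 0.108 against 0.0332, a difference of 0.0748. There 1097 genes were higher with both (195 if independent), 1102 lower with both (204) and 2 opposite. In KCl the correlation was 0.602 against 0.498 simulated (covariance 0.0812 against 0.0327, a difference of 0.0485), with 743 higher with both (126 if independent), 621 lower (103) and 16 opposite. In AT-3 the correlations were 0.443 and 0.46, below the simulated 0.503 and 0.5, though the covariances were above them by 0.0244 and 0.00764. Both compounds raised 6 and 3 genes there (0.328 and 0.0219 if independent), lowered 0 and 0, and moved 1 and 0 in opposite directions. The simulated covariances estimate what sharing gives. With 3 control libraries the controls could not be split with 2 on each side, so part of the excess in overlaps may come from them. Pairs that share no library are free of this. They correlated at 0.335 and 0.339 in E0771 (covariance above the simulated by 0.0496 and 0.048) and at 0.128 and 0.144 in AT-3 (by 0.017 and 0.0211). The 95% interval of the difference between compounds lay within ±0.5 log2 for 58.6 and 60.4% of AT-3 genes without and with KCl, and for 68.4 and 67.5% of E0771 genes. For the rest a difference of that size is not ruled out, so a gene that missed the threshold was not shown to respond alike.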

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

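The tests of between-line differences were chosen before the data were examined; the look at the human-form IDs and the omission of single libraries from the list tests were chosen after seeing results. The 2 lines answered the same treatments differently, and the deposited labels give no reason for it. The effect of KCl differed for 1458 genes, that of NS11021 for 637 and that of BMS204352 for 800. These counts rest on 3 libraries per group, and separate origins of the replicates are not stated, so p-values measure the spread between these samples, which may be technical: the counts for NS11021 and BMS204352 were 1031 and 1296 under DESeq2, 270 for NS11021 without E0771 NS11021 replicate 2, and 141 for BMS204352 with only the libraries compared.

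Under NS11021 the lists of ER chaperones and of HIF1 genes differed between the lines even with an estimated correlation (adjusted p = 0.0284 and 0.0409), both lower in E0771 relative to AT-3. Each of these 2 calls was lost in 7 of 12 omissions of 1 library, at most to 0.0705, and kept in all 12 at the preset correlation. The HIF1 list stood highest in AT-3 in NS11021 replicate 2 (mean log2 level 0.67, against 0.07 and 0.23) and KCl+NS11021 replicate 2 (0.50, against −0.02 and 0.09). With 1 library left out 12 to 23 of 35 members differed, fewest without the former. Ccn2 responded to BMS204352 more negatively in E0771 than in AT-3 by −1.65 log2. That call was lost when any 1 of 4 libraries was left out. The table also held 6 counts on gene IDs of human form, 4 in AT-3 KCl replicate 2 and 2 in AT-3 KCl replicate 3; they were not analysed here and are too few to change any value.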

How the results depend on the processing

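Halved counts, the omission of the replicate 3 libraries of BMS204352 and KCl+BMS204352 and the omission of single libraries from the list tests were tests chosen after seeing results; the others were chosen before the data were examined. Size factors from DESeq2 and halved counts moved no count of genes by more than 1.5 times.

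DESeq2's Wald test called more genes where the main test called few. In AT-3 it gave 70 for NS11021, 1375 for BMS204352, 14 for KCl+NS11021 against KCl, 510 for KCl+BMS204352 against KCl, 905 for NS11021 against BMS204352 and 241 for that contrast in KCl. In E0771 it gave 96 and 406 for the interactions of KCl with NS11021 and BMS204352, and for differences between lines 1031 (NS11021) and 1296 (BMS204352). Without a filter the counts were 7 for KCl+NS11021 against KCl in AT-3 and, in E0771, 419 for NS11021 against BMS204352 and 122 and 415 for the interactions.

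The replicate numbers were not used as pairs, since pairing asked that every same-number correlation exceed 0.1. In deviations from group means, 3 of 45 same-number pairs correlated above 0.1 in AT-3 and 1 of 45 in E0771. The 3 in AT-3 are all the pairs of BMS204352 with KCl+BMS204352 (0.139, 0.115 and 0.34), so these 2 groups alone met that bar. Yet samples are listed by number, and 17 of 18 AT-3 and 12 of 18 E0771 libraries correlated best within their own number. This points to a small shared effect of the number, clearest in AT-3, that the main counts omit. With the number as a block, AT-3 counts rose to 1124 for KCl, 42 for NS11021, 1455 for BMS204352, 8 for KCl+NS11021 against KCl, 620 for KCl+BMS204352 against KCl, and 894 and 303 for NS11021 against BMS204352 without and with KCl. In E0771 they were 53 and 335 for the interactions, and 1056 and 1313 for the line differences in NS11021 and BMS204352.

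With only the libraries of the groups compared, AT-3 gave 83 for NS11021, 10 for BMS204352, 23 for KCl+NS11021 against KCl, and 14 and 189 for NS11021 against BMS204352 without and with KCl. E0771 gave 0 for NS11021 against BMS204352 and 235 and 111 for the interactions, and the line differences were 1143 for NS11021 and 141 for BMS204352. The dispersions then come from fewer libraries, and in these BMS204352 comparisons replicate 3 weighs more; the cause was not tested.

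Without the replicate 3 libraries the counts in AT-3 were 449 for BMS204352, 268 and 106 for NS11021 against BMS204352 without and with KCl, and 6 for the interaction of KCl and BMS204352. In E0771 they were 1081 for NS11021 against BMS204352 in KCl and 373 for the interaction. The direction of 4 list tests turned, none of which was called with all libraries. ATF4 genes in NS11021 against BMS204352 turned in AT-3 (adjusted p = 0.00146), in AT-3 with KCl (0.00542) and in E0771 (1.44e-06), and G2/M genes turned in the AT-3 interaction of KCl and BMS204352 (0.00755). ATF4 genes in E0771 with KCl stayed lower (0.0017).

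Leaving out 1 library at a time, the lowest and highest counts in AT-3 were 393 and 507 for KCl, 0 and 8 for NS11021, 146 and 1743 for BMS204352, 0 and 3 for KCl+NS11021 against KCl, 20 and 214 for KCl+BMS204352 against KCl, 79 and 1070 for NS11021 against BMS204352 and 4 and 61 for that contrast in KCl. In E0771 they were 4045 and 4428 for KCl, 2553 and 2972 for NS11021, 2183 and 3005 for BMS204352, 1576 and 1728 for KCl+NS11021 against KCl, 1759 and 2408 for KCl+BMS204352 against KCl, 109 and 406 for NS11021 against BMS204352, 356 and 602 in KCl, and 6 and 23, and 83 and 322, for the interactions with NS11021 and BMS204352. For the line differences they were 1078 and 1434 (KCl), 270 and 552 (NS11021) and 556 and 1205 (BMS204352). Fewer libraries also mean less power, which lowers most of these counts.

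Of 600 list tests, 200 passed with the preset correlation and 19 with an estimated one. With a filter of 1 CPM, the correlation between lines was 0.19 for NS11021 and 0.227 for BMS204352. Of 888 named-gene calls, 245 were lost at least 1 time when a library was left out and 0 changed sign. With only the libraries compared 180 of the 888 were lost, without the replicate 3 libraries 57 of 459, and with the number as a block 8 were lost and 106 gained.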

Other observations

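The regrouping of samples, the larger-dose test, the spread test and the replicate 3 test of the MRTF-SRF list were planned before their results were seen; the sorting of splits by arm and the tests of depth, swapped libraries, the size of the NS11021 response, fibroblast RNA, the KCl arm and Kcnma1 were chosen after seeing results. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05; in each, 1 of 10 splits, the real one, called as many genes as the real grouping. Real counts and the highest of the other splits in AT-3 were 714 and 25 (KCl), 11 and 0 (NS11021), 779 and 0 (BMS204352), 3 and 0 and 183 and 0 (each compound in KCl), and 434 and 0 and 67 and 0 (compound against compound). In E0771 they were 4860, 3515, 3028, 2304 and 2663 against 0, 235 against 3, and 661 against 0. Each other split put libraries of both groups on each side, which widens the fitted spread where the groups differ. Its low count then follows in part from the real difference and is no measure of chance alone. In AT-3 the interactions called 0 genes, which all 100 splits match by design, so the splits decide nothing there (highest other 0 for NS11021 and 456 for BMS204352). In E0771, 10 and 8 of 100 splits called as many genes as the interactions' 29 and 217 (highest other 1606 and 1234). For the line differences 8, 8 and 5 of 100 matched 1458, 637 and 800 (highest other 2995, 1346 and 1776). Taken as they stand, these shares do not exclude chance for these 5. All of the other splits that matched had the groups of 1 arm whole and mixed those of the other (14 of 100 drawn). Such splits leave the effect of 1 arm in place, so their calls follow from that effect by construction. They are no measure of chance, so the share over all 100 splits decides nothing for these 5. None of the 85 splits that mixed both arms matched, the highest being 0 and 0 for the interactions and 2, 1 and 117 for the line differences. Those splits put treated and control libraries into the same group. This widens the fitted spread and lowers the counts whether or not the effects of the arms differ, so they cannot decide it either.

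The replicate 3 libraries of BMS204352 and KCl+BMS204352 stood apart in AT-3, and that of BMS204352 did in E0771. In E0771 KCl+BMS204352 replicate 3 stood apart less (PC2 at 15.2 against 0.179 and 3.93, PC3 at 15.9 against 6.35 and 11.3). A larger dose of the same response may account for it in AT-3, where their deviations from replicates 1 and 2 correlated with the BMS204352 effect of the other arm at 0.123 and 0.156, which leaves it open. In E0771 these were 0.0552 and 0.0892, under the bound of 0.1 set beforehand for excluding it. That test ran over all tested genes, which can dilute those that respond. Over genes called in the other arm, both libraries lay beyond their own group and away from the controls (by 0.13 and 0.17 of the distance, and by 0.47 and 0.63 in AT-3). These genes were called with all libraries, the other arm's replicate 3 included. The 2 replicate 3 libraries also deviated together (r 0.155 in E0771 and 0.34 in AT-3), so any effect they share could give these distances. The distances therefore cannot decide on a larger dose in either line. In E0771 only the planned test bears on it, with that limit, and it went against a larger dose. Sequencing depth was excluded in both lines, as 0 of the 2 libraries had a total outside the range of the other 16. A swap with any of the 5 other treatments of the line was excluded, since at least 68.9% of the genes tested in AT-3 and 66.3% in E0771 lay nearer to the library's own group. A swap with a sample from outside stays open.

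NS11021 changed 11 genes in AT-3 and 3515 in E0771. For 2235 genes chosen and signed in the E0771 KCl arm, the median change in AT-3 was 0.139 of that in E0771 (95% interval over resampled genes 0.119 to 0.165). For these genes a wider spread between AT-3 libraries was not the whole cause. The test cannot see a response of AT-3 in other genes or in the other direction, and its interval leaves out the spread between libraries. For the count of genes as a whole a wider spread stays open. Simulated log2 changes of 0.30 were recovered at 14% in AT-3 and 54% in E0771. For the HIF1 list the bar set for excluding a smaller response in AT-3 was not met. Its median was 0.34 in AT-3 and −0.17 in E0771, but the AT-3 rise was largest in NS11021 replicate 2 (mean log2 level 0.67 against 0.07 and 0.23) and was 0.23 without it. Without that library the line difference of the list had an adjusted p of 0.0663 with an estimated correlation. Still, all 3 NS11021 libraries lay above DMSO (−0.09, −0.08 and −0.16). Those with KCl (−0.02, 0.50 and 0.09) lay above KCl (−0.09, −0.14 and −0.12). These values argue against a smaller change in the same direction as E0771, for this list and these libraries. The size of the line difference stays unsure.

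MRTF-SRF targets in E0771 were higher with NS11021 than with BMS204352. The replicate 3 libraries were excluded as the source, because the list's median kept 0.73 of its size without them (0.17 to 0.12). Fibroblast RNA stays open in both arms. Of 14 fibroblast transcripts listed 9 were tested, and Dcn, Lum, Col14a1, Clec3b and Mfap5 were not. The median of the 9 was 0.11 without KCl (SE 0.22, from −0.52 to 1.10) against 0.17 for the MRTF-SRF list, and 0.29 with KCl (SE 0.22, from −0.45 to 1.12) against 0.21. The markers were mixed without and with KCl: Pdgfra −0.17 and −0.15, Pdgfrb 0.02 and 0.32, Dpt −0.52 and 0.68. The fibroblast list also rose with KCl alone, so a change within E0771 cells cannot be told apart from fibroblast RNA. The marker Ly6c1 was higher with NS11021 without KCl (1.13 ± 0.21), and with KCl the list of fibroblast markers was (adjusted p = 0.011 with an estimated correlation). A difference between the compounds is open beside it: the KCl arm, which shares no library with the other, showed the higher MRTF-SRF list too (adjusted p = 0.011). The mitochondrial share also separated the compounds there (0.725 to 0.750% with KCl+NS11021, 0.789 to 1.03% with KCl+BMS204352), so RNA quality stays open in that arm. The difference remains a hypothesis that protein or actin measurements could test.

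The openers changed genes although Kcnma1, the gene of their shared target, stood at 0.152 CPM in AT-3 DMSO libraries, under 1 CPM in both lines. Such a low mRNA level leaves open action through little channel protein or through other targets, and RNA alone cannot choose between them.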
